A study of Homo sapiens with 12 samples.

How the data were processed

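The series holds 12 RNA-seq libraries of H9, an established human embryonic stem cell line, and of neurons induced with the proneural transcription factor NGN2, the product of the gene NEUROG2. The labels of the neurons give human embryonic stem cells as their source and name no line, while the series title names induced pluripotent stem cells. The labels were followed, and whether H9 is the parent line of the neurons stays open. The labels give 4 groups of 3 libraries: undifferentiated H9 cells at day 0, neurons induced without pre-patterning at day 21, neurons pre-patterned with SB431542 and CHIR99021 at day 21 (SB-CHIR) and neurons pre-patterned with SB431542 and LDN193189 at day 21 (SB-LDN). Groups and replicate numbers were taken from the sample titles, where the libraries of each group are numbered Exp1 to Exp3 and the unpatterned neurons carry the word Normal. Per the labels' protocols, total RNA was purified with the Qiagen RNeasy kit and treated with DNase, polyadenylated RNA was selected with oligo-dT beads, complementary DNA was made with random primers, and the libraries were sequenced on a BGISEQ-500. The protocols do not say that the libraries kept the strand, so values of a gene and of an overlapping antisense gene cannot be told apart.

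Per the file headers, the deposited table holds FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, 1 value per gene and library, for 21843 genes with NCBI gene identifiers. The submitters' processing notes name the human build hg19 and the programs HISAT, Bowtie2 and RSEM, without versions or the role of each. The deposited table lists the RefSeq transcripts of each gene, and the annotation release is not given in the sources used here. Per the file headers, each library has a column of its own, and 0 columns of values were left unused. Of the gene identifiers, 21689 were found in the RefSeq gene table of assembly GRCh38, which was used for names only. That assembly is not the build named by the submitters, so no coordinates are given. The 54 genes with no symbol stayed in the tests and out of the named genes.

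FPKM values are not counts, so no count model was used. Fragments per library were estimated from the steps between low FPKM values, which depend on the value of 1 fragment and on transcript length. The estimates ranged from 20.4 to 24.6 M fragments per library and are approximate, because the estimated counts behind the values need not be whole. Values were transformed to log2(FPKM + 1), and a gene was tested when it reached an FPKM of 1 in at least 3 of the 12 libraries, which left 14946 genes. All 12 libraries entered 1 linear model with the group as its only term, in limma 3.58.1 under R 4.3.3 with empirical Bayes moderation. The 6 comparisons were each adjusted over the tested genes by the Benjamini-Hochberg method. A gene was called when its adjusted p was below 0.05 and its absolute log2 difference was at least 1. A difference on the log2(FPKM + 1) scale understates the change of a gene with low values.

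Before the data were examined, the groups, the model, the alternatives, a panel of 26 genes, the rule for naming genes and 35 gene lists with 547 entries were fixed. The named genes are those of the panel, the 5 called genes with the largest positive and the 5 with the largest negative log2 difference in each comparison among those whose groups did not overlap, and for each list up to 4 called members with the largest absolute difference, or all where 5 or fewer were called. Some of the genes that this rule takes are not reported here. Genes named outside that rule are described as chosen after their values were seen. The lists covered pluripotency, cell cycle, neural progenitor, pan-neuronal, proneural cascade, presynaptic, postsynaptic, voltage-gated channel, ionotropic glutamate receptor, glutamatergic, GABAergic, cholinergic motor, monoaminergic, telencephalic and anterior, cortical projection neuron, diencephalic, midbrain and isthmus, hindbrain without HOX genes, HOX paralogs 1 to 5, HOX paralogs 6 to 13, caudal axial progenitor, dorsal interneuron, neural crest, peripheral sensory neuron, autonomic and visceral, astrocyte and oligodendrocyte, mesenchyme and fibroblast, endoderm, epithelium, WNT target, BMP and TGF-beta target, retinoic acid response, immediate early, unfolded protein and integrated stress, and mitochondrially encoded genes. Of their entries, 530 had a value and 375 were tested. The lists overlap, and ISL1, POU4F1, LHX9, TLX3, PHOX2A, LHX2 and DBH are among the genes that stand in more than 1 of them. Calls of lists that share genes are thus not separate results. Lists with at least 3 tested members, 32 in all, were compared with the other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison, and again with the correlation estimated for each list. HOXC8 of the panel, HOXA6, HOXA11, HOXB6, HOXB13, HOXC12, HOXD12 and the mitochondrially encoded genes were not analysed here.

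The procedure was tested on simulated data for the comparison of SB-LDN with unpatterned neurons, with 14946 genes, 200 of them changed, in 10 simulations. It called 47.4% of genes changed 2-fold, which lie at the required difference, 97.6% of those changed 3-fold, 99.2% of those changed 4-fold and 100% of those changed 8-fold. There were 2 false calls per simulation on average and 0 calls with the wrong sign, and a list shifted by a log2 difference of 1 was found in 10 of 10 simulations. The simulated genes were independent and had the spread that the model estimated. These rates therefore do not cover correlated genes or libraries that deviate in many genes. The changes were added on the log2(FPKM + 1) scale, so the folds are those of FPKM + 1. A gene with low values needs a larger change of its FPKM to be called at these rates.

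The alternatives were a pseudocount of 0.1, no filter on low values, median-of-ratios scaling, scaling of each library to TPM, a fit of only the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. TPM values are larger than FPKM values here, while the pseudocount and filter stayed the same, so that scaling also gives low genes more weight. Figures were drawn with Matplotlib 3.10.9 and NumPy 2.4.6 under Python 3.11.15. Summed HOX expression was compared between groups of 3 with two-sided exact permutation tests, which cannot give a p below 0.1.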

Results

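Gene expression was measured by RNA-seq in 12 libraries of the human embryonic stem cell line H9 and of neurons made from human embryonic stem cells by induction of NGN2, the proneural transcription factor encoded by NEUROG2. The labels of the neurons name no line, so a difference between lines may be part of each difference from H9. The 4 groups of 3 libraries were undifferentiated H9 cells at day 0, neurons induced without pre-patterning at day 21, and neurons whose starting cells had been pre-patterned with SB431542 and CHIR99021 (SB-CHIR) or with SB431542 and LDN193189 (SB-LDN), also at day 21. SB431542 inhibits the TGF-beta and activin receptors, CHIR99021 inhibits GSK3 and so activates WNT signalling, and LDN193189 inhibits the type I BMP receptors. The title of the series names the question, whether patterning before conversion gives neurons of different regions of the central nervous system. Values are FPKM, given as mean ± SD of 3 libraries, and differences are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The estimated depth ranged from 20.4 to 24.6 M fragments per library. It was lowest in SB-CHIR, at 20.4 to 20.6 M, against 21.7 to 24.1 M in unpatterned neurons, 23.6 to 23.9 M in SB-LDN and 24.2 to 24.6 M in H9. Depth thus moved with the group in the comparisons of SB-CHIR.

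The neuron groups separated from H9 along the first principal component, which held 83.8% of the variance. SB-CHIR separated from the other neurons along the second, which held 8.93%, and unpatterned from SB-LDN neurons along the third, which held 2.78%. Correlations of log2 values within a group were 0.978 to 0.994 and those between groups 0.55 to 0.977, and no 2 libraries were duplicates, since the closest pair shared 0.597% of their values. The sample titles number the libraries Exp1 to Exp3 in each group, and nothing else in the labels says what the numbers stand for or whether replicates were separate cultures. Thus p-values measure only the spread between these libraries. Under TPM scaling, the median of all tested genes against H9 moved from -0.04 to 0.22 for unpatterned neurons, from 0.03 to 0.26 for SB-CHIR and from -0.07 to 0.17 for SB-LDN, so differences from H9 smaller than that are not read as changes.

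**Figure D1:**
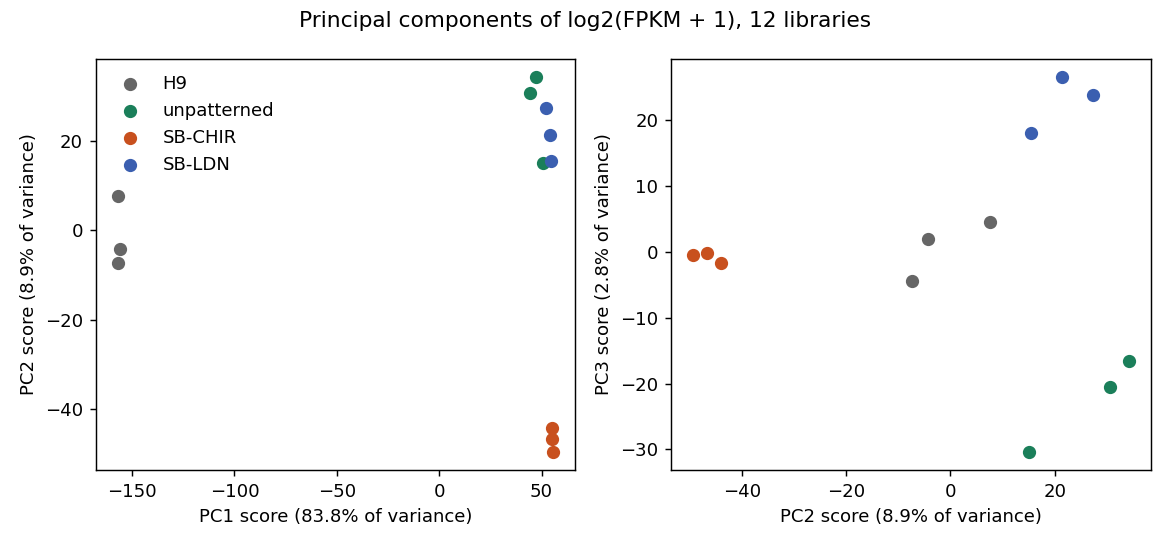
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library coloured by group, the first component (83.8% of the variance) against the second (8.93%) on the left and the second against the third (2.78%) on the right. H9 lies apart along the first, SB-CHIR along the second, and unpatterned and SB-LDN neurons are apart along the third.

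Undifferentiated and converted cells were compared first, with the stem cells as the background of the neurons. In unpatterned neurons, NEUROG2 (gene identifier 63973), the induced factor, rose from 2.52 ± 0.306 FPKM in H9 to 4531 ± 104 (n = 3 each). Its values cannot separate the introduced NGN2 sequence from the endogenous gene. STMN2, a neuronal microtubule regulator, rose from 1.94 ± 1.07 to 1794 ± 49.1, and the microtubule proteins TUBB3 and MAP2 rose from 48.8 ± 12.0 to 1088 ± 71.3 and from 3.52 ± 1.27 to 281 ± 30.7. The pluripotency factor POU5F1 fell from 883 ± 88.8 to 2.59 ± 0.444, and NANOG fell from 50.1 ± 16.7 to 0.613 ± 0.256. SLC17A6, a vesicular glutamate transporter, rose from 0.137 ± 0.0115 to 155.7 ± 9.91, SLC17A7, another of that family, rose from 2.61 ± 0.550 to 31.1 ± 3.24. GAD1, which makes GABA, stayed too low to be tested at 0.177 ± 0.186 in H9 and 0.293 ± 0.107 in the neurons.

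By limma, 3100 genes were higher and 3839 lower in unpatterned neurons than in H9, and 8007 did not pass. The groups did not overlap for 79.7% of the tested genes, where chance gives 10%. The genes higher made up 44.7% of the calls, and 55.3% under TPM scaling, with 4483 higher and 3630 lower. The largest increases were those of NEUROG2 (log2 difference 10.33, SE 0.125, adjusted p 4.3e-14), STMN2 (9.32), HMP19 (8.26), RTN1 (8.04) and STMN4 (7.81), of which RTN1 and STMN4 encode a reticulon and a stathmin of neurons. The largest decreases were those of TDGF1, a NODAL co-receptor (-8.07), POU5F1 (-7.95), the interferon-induced membrane protein gene IFITM1 (-7.77), ESRG (-7.67) and MFGE8 (-7.38). IFITM1 is uncertain, since 31.8% of the 25-base words of its transcripts occur in those of IFITM2 and reads can be split between them.

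Neuronal lists rose and stem cell lists fell in unpatterned neurons. Of 24 pan-neuronal genes tested, 23 rose and 1 did not pass, among them STMN2, STMN4, DCX (7.49) and NEFL (7.42), with camera adjusted p 1.38e-11, and adjusted p = 0.0101 with an estimated correlation. All 24 cell cycle genes fell, led by BUB1 (-6.41) and UBE2C (-6.40), with camera adjusted p 2.37e-10 and adjusted p = 0.0697 with an estimated correlation. Of 18 pluripotency genes, 17 fell (adjusted p 1.93e-07 by camera), and of 23 peripheral sensory neuron genes, 19 rose and 1 fell (6.55e-08), with PRPH (7.22), P2RX3 (6.96), ISL1 (6.56) and POU4F1 (6.35) in front. Both calls held with an estimated correlation, at adjusted p = 0.0101 for each, as did that of the cholinergic motor list, in which 6 of 7 genes rose, ISL2 and SLC18A3 among them (0.00073 and adjusted p = 0.0422 with an estimated correlation). These counts, and those of all lists in this comparison except the telencephalic one, were identical when adjusted over the list alone.

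The other lists that passed camera against H9 in unpatterned neurons lost their call with an estimated correlation. Of 21 presynaptic genes 20 rose, SYT4 (7.28) and SNAP25 (6.01) among them, and of 15 proneural genes 12 rose, NEUROG2, EBF3 (7.80) and NHLH1 (6.46) among them, with adjusted p 1.7e-08 and 1.56e-06 by camera and adjusted p = 0.0639 with an estimated correlation for both. Of 22 voltage-gated channel genes 15 rose, SCN3B and SCN3A in front (5.19e-06, and adjusted p = 0.051 with an estimated correlation). Of 13 ionotropic glutamate receptor genes 9 rose (0.000198), and all 11 epithelial genes fell, CDH1 (-6.17) and CLDN6 (-6.09) among them (1.69e-05), with adjusted p = 0.0639 with an estimated correlation for each. Of 16 postsynaptic genes 9 rose (0.0037), of 5 glutamatergic genes 3 rose (0.0223) and of 10 autonomic and visceral genes 7 rose and 1 fell (0.0285), and each had adjusted p = 0.084 with an estimated correlation.

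Several regional lists were also higher by camera in unpatterned neurons than in H9. Of 12 dorsal interneuron genes 8 rose and 1 fell, with LHX9 (6.42), POU4F1 and TLX3 (4.87) in front (camera adjusted p 0.00143, and adjusted p = 0.124 with an estimated correlation). Of 6 hindbrain genes 5 rose, NKX6-1 (4.51), PHOX2A (1.61) and TBX20 among them, the last listed at 0 in each H9 library (camera adjusted p 0.00901, and adjusted p = 0.0962 with an estimated correlation). Of 15 cortical projection neuron genes 8 rose, LMO3 (5.38) in front (0.0102, and adjusted p = 0.101 with an estimated correlation). Of 10 diencephalic genes 6 rose and 1 fell (0.0285, and adjusted p = 0.231 with an estimated correlation), and of 3 midbrain and isthmus genes POU4F1 and PAX2 rose (0.0316, and adjusted p = 0.161 with an estimated correlation). The midbrain, hindbrain and autonomic calls ended under TPM scaling, with adjusted p 0.104, 0.0569 and 0.0537, and the first 2 also without the filter, at 0.35 and 0.0566. Over all alternatives the adjusted p of these lists ranged from 0.0257 to 0.35, from 0.00365 to 0.0569 and from 0.0201 to 0.0537.

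No call was made by camera for the remaining lists in unpatterned neurons against H9. Of 12 neural progenitor genes 1 rose and 6 fell, SOX2 (-4.82) in front (adjusted p 0.107). Of 10 telencephalic and anterior genes 6 fell, and 5 when adjusted over the list alone, with OTX2 (-5.30) and ZIC2 (-4.43) in front (0.11). Of 11 neural crest genes 3 rose and 7 fell (0.123), SOX10 among the latter, from 1.41 ± 0.0907 to 0.01 ± 0.01. The mesenchyme and fibroblast list had 6 of 8 genes lower (0.165), the astrocyte and oligodendrocyte list 1 higher and 5 lower of 9 (0.241), and the GABAergic list SST and CALB2 higher of 3 (0.11). HOXB2 rose (2.21) and HOXB3, listed at 0 in each H9 library, reached 1.89, 2.80 and 2.04 FPKM, among 4 tested HOX genes of paralogs 1 to 5 (0.123). The other counts were 3 of 6 monoaminergic genes higher (0.443), 2 higher and 3 lower of 5 caudal axial genes (0.834), 4 of 8 WNT targets lower (0.079), 2 higher and 6 lower of 13 BMP and TGF-beta targets (0.144). Of the rest, 2 were higher and 4 lower of 8 retinoic acid genes (0.819), 2 higher and 3 lower of 10 immediate early genes (0.599), and 4 higher and 4 lower of 13 unfolded protein genes (0.74). HOX paralogs 6 to 13, endoderm genes and mitochondrially encoded genes had no tested members in any comparison.

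Some anterior genes were high in 1 of the H9 libraries. The forebrain regulators SIX3 and FEZF1 stood at 26.6 and 69.4 FPKM in H9 replicate 1, against 0.55 and 3.64 in replicate 2 and 0.64 and 0.79 in replicate 3. SIX3 differed by -0.28 between unpatterned neurons and H9, and by 1.09 without H9 replicate 1 (limma adjusted p 2.41e-06, and 2.41e-06 to 0.943 over its alternatives). FEZF1 fell by 2.26, and by 0.72 without that library, below the required difference. The call of FEZF1 also ended without any 1 of the unpatterned replicates, with adjusted p 0.0891, 0.0852 and 0.0661, under TPM scaling and in a fit of only the 6 libraries, and its adjusted p ranged from 0.00265 to 0.125 over its alternatives.

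Both pre-patterned groups were compared with H9 as well. NEUROG2 rose to 138.6 ± 15.7 FPKM in SB-CHIR (log2 difference 5.31) and to 6591 ± 1177 in SB-LDN (10.86). STMN2 rose to 1705 ± 52.2 in SB-CHIR and to 1585 ± 103 in SB-LDN, with TUBB3 at 906 ± 92.2 and 997 ± 84.3 and MAP2 at 273 ± 20.4 and 325 ± 34.6. POU5F1 fell to 5.09 ± 0.306 in SB-CHIR and to 2.09 ± 0.356 in SB-LDN, and NANOG fell to 1.25 ± 0.0462 and 0.487 ± 0.156. NEUROG3, a paralog of NEUROG2 known from endocrine progenitors, rose to 228 ± 17.6 in SB-CHIR from 0.167 ± 0.118 in H9 (7.62).

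By limma, 3796 genes were higher and 3781 lower in SB-CHIR than in H9, with 7369 not passing, and 3156 were higher and 3931 lower in SB-LDN than in H9, with 7859 not passing. TPM scaling gave 5160 higher and 3750 lower in SB-CHIR and 4466 and 3822 in SB-LDN, and median-of-ratios scaling gave 3528 and 4029, and 3277 and 3839. The balance of higher and lower genes thus depends on the processing in both groups, where TPM scaling also gives low genes more weight. Groups did not overlap for 84.1% and 80.04% of the tested genes, where chance gives 10%. Behind NEUROG2 in SB-LDN, STMN2 (9.25 in SB-CHIR and 9.14 in SB-LDN), HMP19 (8.36 and 8.43), RTN1 (7.99 and 8.01) and STMN4 (7.71 and 7.60) had the largest increases in both groups. The largest decreases in SB-CHIR were those of MFGE8 (-8.46), IFITM1 (-8.11), MGST1 (-8.06), IFITM2 (-8.00) and TDGF1 (-7.86), and those in SB-LDN of TDGF1 (-8.21), POU5F1 (-8.16), ESRG (-7.92), the RNA-binding protein gene LIN28A (-7.85) and MFGE8 (-7.73). The split of reads between IFITM1 and IFITM2, which share sequence, is uncertain.

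In SB-CHIR against H9, all 24 pan-neuronal genes rose and 17 of 18 pluripotency genes fell, and both camera calls held with an estimated correlation (1.12e-10 and 2.63e-07, and adjusted p = 0.0207 with an estimated correlation for both). All 24 cell cycle genes (1.12e-10) and all 11 epithelial genes (1.56e-05) fell. The genes that rose were 20 of 21 presynaptic (1.7e-07), 12 of 15 proneural (1.48e-05), 15 of 22 channel (3.78e-05), 9 of 13 ionotropic glutamate receptor (0.000149), 5 of 5 glutamatergic (0.018) and 4 of 7 cholinergic genes (0.00961), and each of these 8 lists had adjusted p = 0.0715 with an estimated correlation. Of 16 postsynaptic genes 10 rose (0.00369, and adjusted p = 0.0796 with an estimated correlation). Of 23 peripheral sensory genes 15 rose and 2 fell (0.000517, and adjusted p = 0.0655 with an estimated correlation). Of 4 HOX genes of paralogs 1 to 5, 3 rose, HOXA2 (4.30) and HOXB2 (1.30) among them (0.0413, 0.0207 to 0.199 over the alternatives with the highest without the filter, and adjusted p = 0.141 with an estimated correlation). Of 12 neural progenitor genes 1 rose and 7 fell (0.0413, and adjusted p = 0.125 with an estimated correlation). That call ended under both scalings and without the filter, with adjusted p 0.0503 to 0.11 in a range of 0.0345 to 0.11 over all alternatives.

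The lists not called in SB-CHIR against H9 included 10 telencephalic genes, of which 1 rose and 6 fell (camera adjusted p 0.0637). That list was called without H9 replicate 2 (0.0488) or 3 (0.0366), under TPM scaling and with a pseudocount of 0.1, with a range of 0.012 to 0.0787 over its alternatives. The midbrain list, with 2 of 3 genes higher (0.0649), was called without SB-CHIR replicate 1 (0.0466) and with a pseudocount of 0.1 (range 0.0418 to 0.467). The BMP and TGF-beta target list, with 2 higher and 7 lower of 13 genes (0.0941), was called without H9 replicate 2 (0.0474, range 0.0474 to 0.14). Counts of genes higher and lower were 5 and 1 of 12 dorsal interneuron (0.0853, called with a pseudocount of 0.1 in a range of 0.0316 to 0.104), 2 and 7 of 11 neural crest (0.0853), 6 and 1 of 15 cortical (0.167), 2 and 2 of 10 diencephalic (0.924), 2 and 0 of 6 hindbrain (0.675), 4 and 1 of 10 autonomic (0.632), 2 and 3 of 5 caudal axial (0.923), 1 and 0 of 3 GABAergic (0.347) and 1 and 0 of 6 monoaminergic genes (0.396). They were 2 and 5 of 9 astrocyte and oligodendrocyte (0.162), 0 and 6 of 8 mesenchyme (0.0941), 1 and 3 of 8 WNT target (0.357), 2 and 4 of 8 retinoic acid (0.699), 2 and 3 of 10 immediate early (0.924) and 4 and 3 of 13 unfolded protein genes (0.924). Adjusted over the list alone, all counts were identical.

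In SB-LDN against H9, 23 of 24 pan-neuronal genes rose (camera adjusted p 1.46e-11) and 17 of 18 pluripotency genes fell (3.5e-07), both with adjusted p = 0.0153 with an estimated correlation. Of 23 peripheral sensory genes 15 rose and 1 fell (1.54e-05), 15 of 22 channel genes (1.49e-06), 10 of 13 ionotropic glutamate receptor genes (2.12e-05) and 7 of 7 cholinergic motor genes rose (0.000471), and these 4 lists also held, with adjusted p = 0.0212, 0.0384, 0.0421 and 0.0359 with an estimated correlation. All 24 cell cycle (2.77e-10) and 4 of 5 glutamatergic genes (0.0135) changed, the former downward and the latter upward, with adjusted p = 0.0611 with an estimated correlation for both. Of the others, 19 of 21 presynaptic (1.42e-08), 12 of 15 proneural (1.49e-06) and 9 of 16 postsynaptic genes (0.000656) rose, 1 postsynaptic gene fell, and all 11 epithelial genes fell (1.54e-05), each with adjusted p = 0.0564 with an estimated correlation. Of 15 cortical genes 9 rose and 1 fell (0.00432, and adjusted p = 0.0786 with an estimated correlation), and of 12 dorsal interneuron genes 8 rose and 1 fell (0.00644, and adjusted p = 0.209 with an estimated correlation).

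The remaining lists were not called in SB-LDN against H9. Of 10 telencephalic genes 3 rose and 5 fell (camera adjusted p 0.664), with SIX3 higher and OTX2 (-3.86) and ZIC2 (-6.28) lower. SIX3 rose by 3.73, and by 5.10 without H9 replicate 1. Counts of genes higher and lower were 2 and 6 of 12 neural progenitor (0.145), 3 and 0 of 3 GABAergic (0.0656), 3 and 0 of 6 monoaminergic (0.194), 7 and 1 of 10 diencephalic (0.121), 1 and 0 of 3 midbrain (0.385), 2 and 0 of 6 hindbrain (0.543), 0 and 0 of 4 HOX (0.601), 2 and 2 of 5 caudal axial (0.961) and 2 and 7 of 11 neural crest genes (0.129). They were 3 and 2 of 10 autonomic (0.664), 2 and 5 of 9 astrocyte and oligodendrocyte (0.4), 0 and 6 of 8 mesenchyme (0.129), 1 and 3 of 8 WNT target (0.203), 1 and 7 of 13 BMP and TGF-beta target (0.194), 1 and 3 of 8 retinoic acid (0.664), 3 and 2 of 10 immediate early (0.664) and 4 and 3 of 13 unfolded protein genes (0.961). Adjusted over the list alone, all counts were identical.

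SB-CHIR and unpatterned neurons were compared to ask what pre-patterning with a TGF-beta inhibitor and a GSK3 inhibitor changed in the resulting neurons. HOXA2, a patterning gene of the hindbrain, rose from 0.04 ± 0.0361 FPKM in unpatterned neurons to 18.9 ± 1.28 in SB-CHIR (n = 3 each). The homeobox gene MEIS2 rose from 2.59 ± 0.127 to 115.5 ± 2.12. LHX9 and ISL1, regulators of diencephalic and dorsal neurons and of sensory and motor neurons, fell from 86.0 ± 2.87 to 0.767 ± 0.117 and from 96.7 ± 3.85 to 1.55 ± 0.144. NEUROG2 fell from 4531 ± 104 to 138.6 ± 15.7 and NEUROG3 (gene identifier 50674) rose from 0.117 ± 0.108 to 228 ± 17.6, while TUBB3 (1088 ± 71.3 and 906 ± 92.2) and MAP2 (281 ± 30.7 and 273 ± 20.4) did not pass. NEUROG2, the induced factor, thus differed between the groups. Its effect on other genes cannot be told apart from that of pre-patterning.

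By limma, 824 genes were higher and 467 lower in SB-CHIR than in unpatterned neurons, and 13655 did not pass. The groups did not overlap for 62.5% of the tested genes, where chance gives 10%. The genes higher made up 63.8% of the calls, and 52.8% under median-of-ratios scaling, with 626 higher and 560 lower. NEUROG3 had the largest increase (log2 difference 7.68, SE 0.106, adjusted p 1.79e-12), and HOTAIRM1 (5.49), MEIS2 (5.02) and HOXA2 (4.26) were also among the largest. HOTAIRM1 is a noncoding gene of the HOXA cluster, and without strand its value of 46.9 ± 2.13 is uncertain. LHX9 had the largest decrease (-5.62, SE 0.141, adjusted p 1.45e-10). ISL1 (-5.26), NEUROG2 (-5.03) and PRPH, a peripheral neuron intermediate filament gene (-4.86), were also among the largest.

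RNA classes also differed between these groups, in genes chosen after their values were seen. The ribosomal RNA genes RNA18S5 and RNA28S5 stood at 21.4 ± 2.63 and 37.5 ± 2.58 FPKM in SB-CHIR, against 1.91 ± 0.378 and 7.53 ± 1.30 in unpatterned neurons and 1.08 ± 0.301 and 8.07 ± 2.21 in SB-LDN. The nuclear noncoding RNAs MALAT1 and NEAT1 stood at 46.0 ± 6.98 and 10.3 ± 0.960 in SB-CHIR, 14.5 ± 8.03 and 5.09 ± 2.54 in unpatterned neurons and 8.60 ± 2.24 and 1.33 ± 0.564 in SB-LDN. With the mean log2 value of MALAT1 and NEAT1 as a covariate over the 9 neuron libraries, 500 genes were higher and 487 lower in SB-CHIR than in unpatterned neurons, and 400 of the 824 were among the 500. That score moves with the group, so the covariate also removes part of the group difference.

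**Figure D2:**
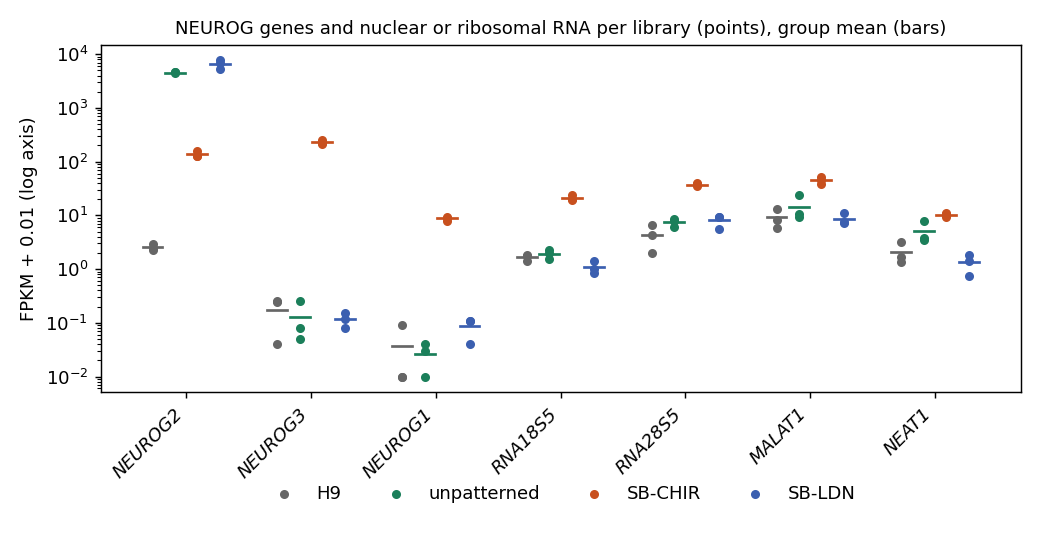
FPKM per library on a log axis for NEUROG2, NEUROG3, NEUROG1, RNA18S5, RNA28S5, MALAT1 and NEAT1, with 1 point per library. In the 3 SB-CHIR libraries NEUROG2 lies at 129 to 157 and NEUROG3 at 216 to 248, whereas in the other 6 neuron libraries NEUROG2 lies at 4412 to 7665 and NEUROG3 at 0.04 to 0.24.

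Several regional lists were lower by camera in SB-CHIR than in unpatterned neurons. Of 23 peripheral sensory neuron genes 14 fell and 9 did not pass, with ISL1, PRPH and TLX3 (-3.82) among the former, and camera's adjusted p of 1.03e-09 became adjusted p = 0.00637 with an estimated correlation. Of 10 diencephalic genes 6 fell, with LHX9, IRX1 (-3.90), SIM1 (-3.65) and BARHL2 (-2.48) in front, and of 12 dorsal interneuron genes 7 fell, with LHX9, TLX3, LHX1 (-3.13) and TLX1 (-3.13) in front. Both had camera adjusted p 1.58e-06 and adjusted p = 0.0605 with an estimated correlation, and adjusted over the list alone the dorsal list had 1 gene higher, LHX5, at 3.90 ± 0.157 and 15.8 ± 0.330 FPKM. Of 6 hindbrain genes outside the HOX clusters 3 fell, among them PHOX2A (-2.56) and TBX20, the last from 1.43 ± 0.301 FPKM to a listed 0 in each SB-CHIR library (3.71e-05, and adjusted p = 0.0551 with an estimated correlation). Of 10 autonomic and visceral genes 5 fell, PHOX2A and the nicotinic receptor genes CHRNB4 (-2.52) and CHRNA3 (-1.59) among them, and DBH rose (0.000974, and adjusted p = 0.0551 with an estimated correlation).

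The cholinergic motor and proneural lists were lower by camera as well in SB-CHIR. Of 7 cholinergic motor genes ISL2 (-3.34), SLC5A7 (-2.41) and CHAT (-1.24) fell (camera adjusted p 0.00493, and adjusted p = 0.0605 with an estimated correlation). Of 15 proneural genes 7 fell, with NEUROG2, INSM1 (-2.37) and EBF3 (-1.79) in front, and NEUROG1 rose by 3.26 (0.0014, and adjusted p = 0.248 with an estimated correlation). Of 12 neural progenitor genes VIM (-1.29), SOX2 (-1.19) and PROM1 (-1.06) fell and the Notch ligand gene DLL1 rose (1.02), with camera adjusted p 0.0381 and adjusted p = 0.19 with an estimated correlation. That call ended under both scalings, without unpatterned replicate 3 (0.0674) and without SB-CHIR replicate 1 (0.0526), in a range of 0.00741 to 0.0923. DLL1 fell short at 0.86 without unpatterned replicate 1, 0.99 without SB-CHIR replicate 1 and 0.91 under median-of-ratios scaling, and PROM1 at -0.998 without unpatterned replicate 3. Of 24 cell cycle genes none passed, with a median of -0.27, and the list was lower by camera (0.0121, adjusted p = 0.553 with an estimated correlation, and 0.11 without unpatterned replicate 3 in a range of 0.00209 to 0.11). Of 16 postsynaptic genes SHANK2 rose (1.36), with the list higher by camera (0.0459, and adjusted p = 0.282 with an estimated correlation), a call that ended without unpatterned replicate 2 (0.0818), unpatterned replicate 3 (0.0674) or SB-CHIR replicate 3 (0.0626), in a range of 0.0276 to 0.0818.

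HOX genes of paralogs 1 to 5 moved in both directions in SB-CHIR relative to unpatterned neurons. Of 4 genes 2 rose, HOXA2 (4.26) among them, and HOXB3 fell (-1.46, from 2.24 ± 0.488 to 0.173 ± 0.0252 FPKM). HOXB2 did not pass at 3.67 ± 0.295 and 1.5 ± 0.318, but passed at -1.002 without SB-CHIR replicate 3 and -1.19 under TPM scaling. Camera made no call over the 4 genes (adjusted p 0.702). Of 10 telencephalic genes ZIC2 fell (-1.97, adjusted p of the list 0.206, called with a pseudocount of 0.1 or without the filter in a range of 0.0428 to 0.468). SIX3 (2.40 ± 0.342 and 0.287 ± 0.0462 FPKM) and FEZF1-AS1 did not pass in the model with H9, with adjusted p 0.179 and 0.195. In a fit of only the 6 libraries they passed at -1.40 and -1.11, with adjusted p 7.03e-05 and 6.36e-05, and up to 0.298 and 0.297 over their alternatives. Of 15 cortical genes BCL11A (-2.14), RELN (-2.14), BCL11B (-1.54) and LMO3 (-1.11) fell (0.141). Of 3 midbrain genes POU4F1 fell (-2.14, list 0.141), and of 5 caudal axial genes FGF17 (2.34) and WNT5B (1.26) rose (0.716). None of 8 WNT targets passed (0.141), and of 13 BMP and TGF-beta targets 3 fell, CTGF (-2.82) and ID4 (-1.78) among them (0.306). Of 8 retinoic acid genes CRABP1 fell (-3.27) and CYP26B1 rose (1.20, list 0.716).

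**Figure D3:**
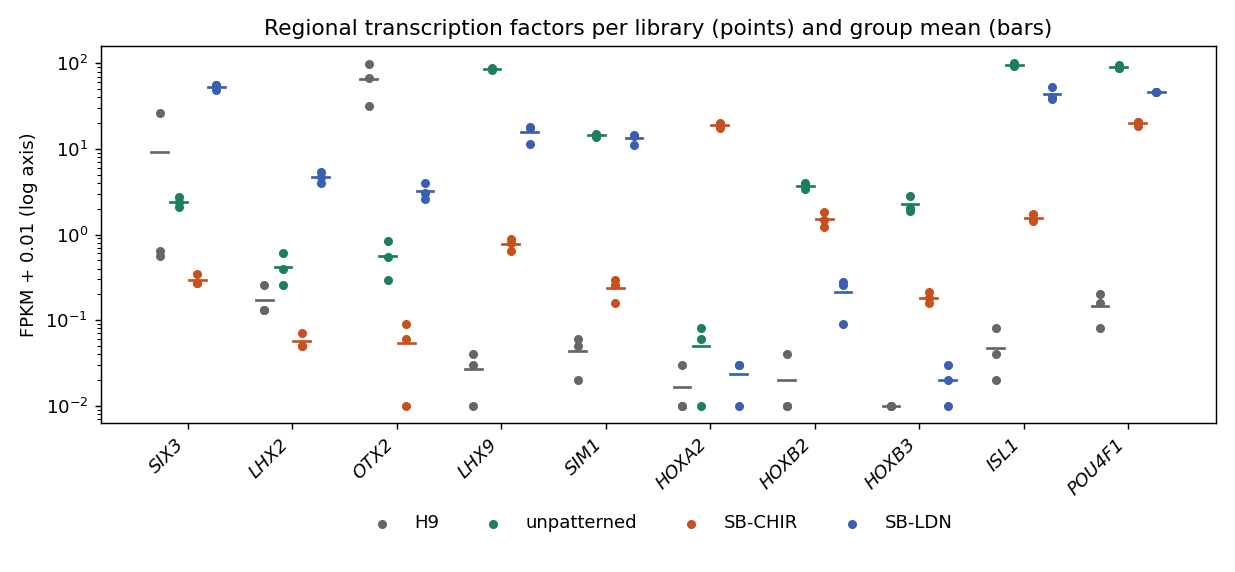
FPKM per library of 10 regional regulators, in part chosen after their values were seen, on a log axis after adding 0.01 so that values of 0 can be drawn, with points for libraries and bars for group means. Group means of SIX3 and LHX2 are highest in SB-LDN, OTX2 in H9, HOXA2 in SB-CHIR, and ISL1, POU4F1, LHX9, HOXB2 and HOXB3 in unpatterned neurons.

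The remaining lists were not called between SB-CHIR and unpatterned neurons. Of 24 pan-neuronal genes ELAVL4 rose (1.94) and MAB21L1 (-2.79), ELAVL2 (-1.54) and NEFM (-1.08) fell (camera adjusted p 0.583). Of 22 channel genes 5 rose, CACNA1A (1.40), HCN2 (1.38) and CACNA1E (1.29) in front, and 2 fell, KCNA1 (-1.49) in front (0.532). Of 13 ionotropic glutamate receptor genes GRIN1 (2.09), GRIN2D (1.87) and GRIA4 (1.11) rose and GRIK3 fell (-2.31, list 0.649), though GRIA4 fell short under median-of-ratios scaling at 0.99. Of 21 presynaptic genes CPLX1 rose (1.80) and SYN3 fell (-1.14, list 0.115), and that list was called without unpatterned replicate 1 (0.0369, range 0.0369 to 0.207). Of 5 glutamatergic genes 1 rose and SLC17A6 fell (-2.95, to 19.4 ± 1.85 FPKM, list 0.808), and SLC17A7 did not pass, at 17.5 ± 1.73. Of 3 GABAergic genes 1 rose and CALB2 (-1.44) and SST (-1.42) fell (0.619), and of 6 monoaminergic genes DBH rose (1.45) and NR4A2 (-1.34) and DDC (-1.28) fell (0.609).

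Lists of other cell types and of stress were not called by camera between SB-CHIR and unpatterned neurons. Of 18 pluripotency genes DNMT3B, a DNA methyltransferase, rose (1.58, list 0.702 by camera). Of 11 neural crest genes TFAP2A (-1.56) and NGFR (-1.17) fell (0.415), and SOX10 did not pass at 0.01 ± 0.01 and 0.113 ± 0.0404. Of 9 astrocyte and oligodendrocyte genes GJA1 fell (-2.01, list 0.609), and of 11 epithelial genes CLDN6 fell (-1.29, and -0.92 without unpatterned replicate 3, list 0.415). Of 10 immediate early genes NR4A1 rose (1.51) and JUN fell (-2.62, list 0.808), and none of 13 unfolded protein genes passed (0.853). Of 8 mesenchyme and fibroblast genes FN1 (-1.73) and COL1A1 (-1.52) fell, and 3 when adjusted over the list alone (0.141). Their calls ended without unpatterned replicate 3, with adjusted p 0.0709 and 0.0504, and for FN1 without unpatterned replicate 1, at 0.0549, in ranges of 0.00151 to 0.0709 and 0.000536 to 0.0504. Unpatterned replicate 2 was low in these genes, with COL1A1 at 0.45 FPKM against 2.55 and 4.28 and TAGLN at 2.56 against 10.2 and 33.1 in replicates 1 and 3. It was high in MALAT1, at 23.8 against 9.25 and 10.5, and without it the list was called (0.0096, range 0.0096 to 0.311), as it was with a pseudocount of 0.1. Except where given, counts adjusted over the list alone were identical.

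SB-LDN and unpatterned neurons were compared to ask what pre-patterning with dual inhibition of TGF-beta and BMP receptors, a treatment used to make anterior neural tissue, changed. The forebrain regulators SIX3 and LHX2 rose from 2.40 ± 0.342 and 0.407 ± 0.172 FPKM in unpatterned neurons to 53.6 ± 3.82 and 4.71 ± 0.685 in SB-LDN (n = 3 each). OTX2, of fore- and midbrain, rose from 0.553 ± 0.280 to 3.21 ± 0.686. PRPH fell from 162.5 ± 15.0 to 7.75 ± 1.98. NEUROG2 did not reach the required difference, at 4531 ± 104 and 6591 ± 1177, and neither did TUBB3 (997 ± 84.3 in SB-LDN), MAP2 (325 ± 34.6), SLC17A6 (111.6 ± 5.55) or SLC17A7 (16.8 ± 2.47).

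By limma, 171 genes were higher and 169 lower in SB-LDN than in unpatterned neurons, and 14606 did not pass. The groups did not overlap for 37.5% of the tested genes, where chance gives 10%. SIX3 had the largest increase (log2 difference 4.01, SE 0.815, adjusted p 0.00573). FEZF1-AS1 (3.55), the neuropeptide precursor gene VGF (3.06) and NRTN, which encodes neurturin (3.03), were also among the largest. FEZF1-AS1 lies opposite FEZF1, and without strand its rise from 1.18 ± 0.159 to 24.5 ± 2.33 FPKM cannot be told from one of FEZF1, which did not pass, at 0.763 ± 0.311 and 11.1 ± 1.22. Among the largest decreases were those of PRPH (-4.24, SE 0.183, adjusted p 6.72e-08), the serotonin receptor gene HTR3A (-3.75), PRLHR (-3.58) and TLX3, a homeobox gene of sensory and dorsal spinal neurons (-3.49). The model's spread includes H9, where SIX3 and FEZF1 stood at 26.6 and 69.4 FPKM in replicate 1. In a fit of only the 6 libraries FEZF1 rose by 2.78 (adjusted p 0.000204), and over its alternatives the adjusted p of FEZF1 ranged from 0.000204 to 0.174.

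The anterior list was higher and several posterior and peripheral lists were lower by camera in SB-LDN than in unpatterned neurons. Of 10 telencephalic and anterior genes 4 rose, SIX3, LHX2 (2.02) and OTX2 (1.44) among them, ZIC2 fell (-1.85) and 5 did not pass, while adjusted over the list alone FEZF1 rose too (camera adjusted p 0.00567, 0.0693 without the filter in a range of 0.00472 to 0.0693, and adjusted p = 0.0582 with an estimated correlation). Of 6 hindbrain genes 3 fell, PHOX2A (-2.53) and TBX20 (-1.27) among them. Of 23 peripheral sensory genes 7 fell, PRPH, TLX3 and POU4F2 (-2.34) in front, and 1 rose. Both lists had camera adjusted p 2.97e-08, with adjusted p = 0.0112 and adjusted p = 0.00872 with an estimated correlation. Of 10 autonomic and visceral genes 7 fell, PHOX2A, CHRNA3 (-1.97) and CHRNB4 (-1.91) among them (1.19e-06, and adjusted p = 0.00872 with an estimated correlation). Of 3 midbrain and isthmus genes PAX2 (-1.14) and LMX1B (-1.01) fell (4.44e-05, 0.258 without the filter in a range of 1.52e-05 to 0.258, and adjusted p = 0.045 with an estimated correlation). LMX1B fell short at -0.93 and -0.98 without unpatterned replicates 1 and 3 and at -0.999 and -0.99 without SB-LDN replicates 1 and 3.

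**Figure D4:**
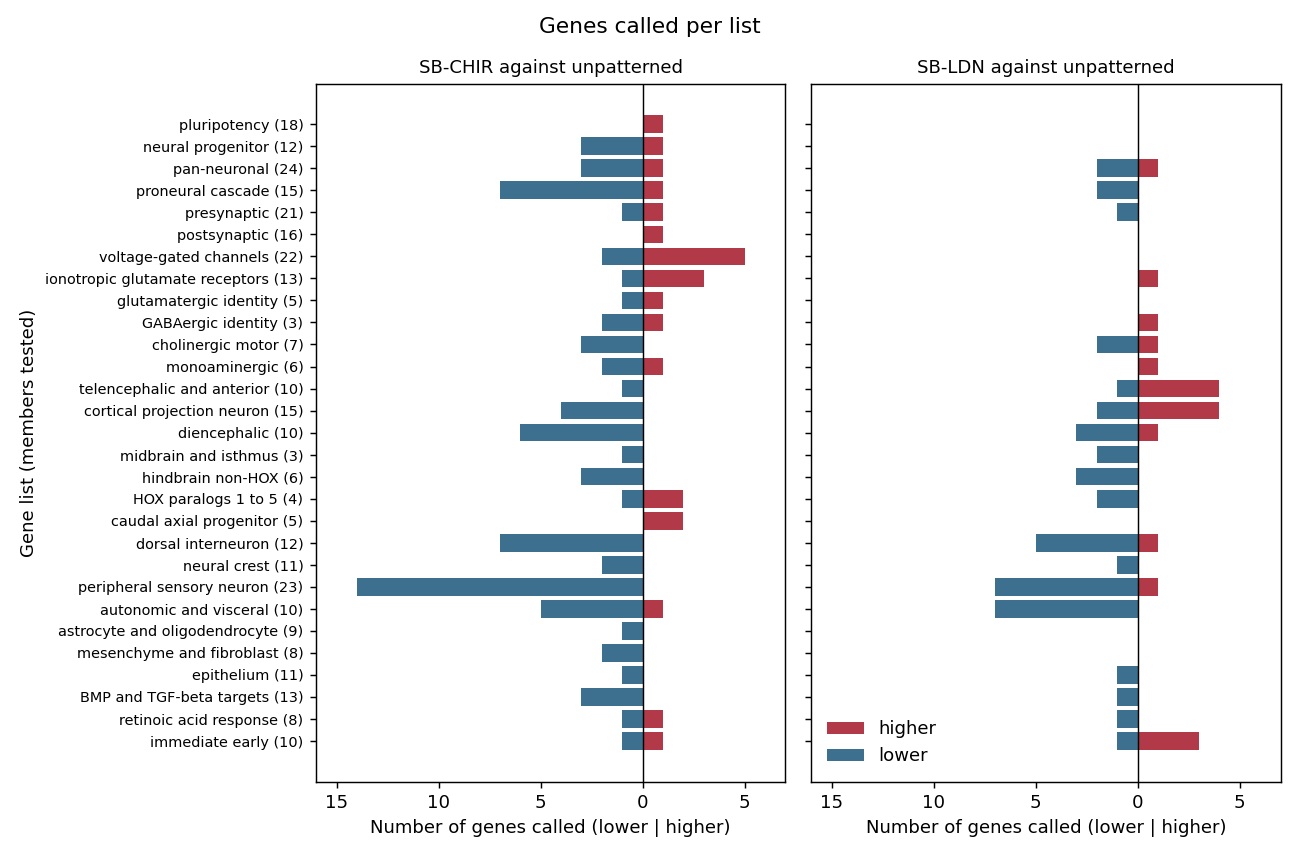
Number of genes called higher or lower per gene list in SB-CHIR and in SB-LDN, each against unpatterned neurons, for lists with at least 3 tested members and at least 1 called gene. The peripheral sensory list has 14 of 23 genes lower in SB-CHIR and 7 lower and 1 higher in SB-LDN, and the autonomic list has 5 and 7 of 10 genes lower.

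Other regional lists were lower by camera in SB-LDN and lost their call with an estimated correlation. Of 12 dorsal interneuron genes 5 fell, TLX3, LHX9 (-2.41) and TLX1 (-1.60) in front, and LHX2 rose (0.00449, and adjusted p = 0.198 with an estimated correlation). Of 10 diencephalic genes LHX9, IRX1 (-1.45) and IRX2 (-1.06) fell and OTP, a hypothalamic regulator, rose (1.99), with adjusted p 0.00709 and adjusted p = 0.218 with an estimated correlation. IRX1 lost its call when any 1 of the 6 libraries was left out, with adjusted p 0.0662 to 0.0903, and ranged from 0.000277 to 0.118 over all its alternatives. Of 4 HOX genes of paralogs 1 to 5, HOXB2 (-1.96, to 0.20 ± 0.104 FPKM) and HOXB3 (-1.67) fell, and HOXA2 did not pass, at 0.04 ± 0.0361 and 0.0133 ± 0.0115 (list 0.0146, and adjusted p = 0.132 with an estimated correlation). None of 24 cell cycle genes passed, with a median of -0.18 (0.0212, adjusted p = 0.4 with an estimated correlation, and 0.361 without unpatterned replicate 3 in a range of 0.00106 to 0.361).

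Several synaptic and transmitter lists were higher by camera in SB-LDN with few genes called. Of 6 monoaminergic genes DDC rose (1.15), and TH did not pass at 1.22 ± 0.269 and 1.97 ± 0.210 (0.00286, and adjusted p = 0.045 with an estimated correlation). Of 13 ionotropic glutamate receptor genes GRIN3A rose (1.62), and none of 8 WNT targets passed (0.00286 and 0.0192, and adjusted p = 0.11 with an estimated correlation for both). Of 3 GABAergic genes 1 rose, and none of 16 postsynaptic genes passed (0.00906 for each, and adjusted p = 0.132 with an estimated correlation for both). Of 21 presynaptic genes SV2B fell by 1.06, and fell short at -0.98 without unpatterned replicate 1, against a list median of 0.31 (0.00567, and adjusted p = 0.326 with an estimated correlation). None of 22 channel genes passed (0.0192, and adjusted p = 0.22 with an estimated correlation). Of 10 immediate early genes FOS (2.49), NR4A1 (1.62) and NPAS4 (1.07) rose and JUN fell (-1.83, list 0.0269, and adjusted p = 0.381 with an estimated correlation). That call ended without unpatterned replicate 3 (0.0548) or SB-LDN replicate 2 (0.0872), in a range of 0.0178 to 0.0872. Without SB-LDN replicate 2 those of FOS (adjusted p 0.0622, range 0.00214 to 0.0622) and NPAS4 (log2 difference 0.94) ended too.

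No call was made by camera for the other lists in SB-LDN against unpatterned neurons. Of 15 cortical genes 4 rose, NR2F1 (1.88), TBR1 (1.81) and POU3F3 (1.36) in front, and 2 fell, BCL11B (-1.27) in front (0.118). Of 24 pan-neuronal genes ELAVL4 rose (1.61) and NEFM (-1.26) and MAB21L1 (-1.05) fell (0.145), and of 15 proneural genes EBF1 (-1.52) and EBF2 (-1.25) fell (0.118, and 0.0429 without SB-LDN replicate 2 in a range of 0.0429 to 0.5). Of 7 cholinergic motor genes MNX1 rose (1.84) and SLC5A7 (-1.84) and ISL2 (-1.46) fell (0.402), and CHAT did not pass, at 3.07 ± 0.200 and 2.29 ± 0.175. Single genes fell among 11 neural crest genes, NGFR (-1.79, list 0.341), 11 epithelial genes, CLDN6 (-1.50, list 0.0708, called under both scalings, with a pseudocount of 0.1 and at 0.00375 without unpatterned replicate 2, in a range of 0.00375 to 0.177), and 8 retinoic acid genes, CRABP1 (-2.12, list 0.496). Of 13 BMP and TGF-beta targets 1 fell, and 2 when adjusted over the list alone (0.496).

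None passed among 18 pluripotency (0.149, called with a pseudocount of 0.1 in a range of 0.0448 to 0.251), 12 neural progenitor (0.401), 5 glutamatergic (0.85), 5 caudal axial (0.332), 9 astrocyte and oligodendrocyte (0.341), 13 unfolded protein (0.0513) and 8 mesenchyme and fibroblast genes (0.0844) in SB-LDN against unpatterned neurons. Adjusted over the list alone, 2 mesenchyme genes were lower, and counts not given otherwise were identical. Without unpatterned replicate 2, the library with low COL1A1 and high MALAT1, the mesenchyme list was called (0.00067, range 0.00067 to 0.323), and the unfolded protein list was called without unpatterned replicate 1 (0.00544) or SB-LDN replicate 3 (0.0251), in a range of 0.00544 to 0.214. Both were also called under TPM scaling, with a pseudocount of 0.1 and with the replicate number as a block, and the latter without the filter.

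The direct comparison of the pre-patterned groups tested the difference between them. NEUROG2 (6591 ± 1177 FPKM in SB-LDN and 138.6 ± 15.7 in SB-CHIR) and SIX3 (53.6 ± 3.82 and 0.287 ± 0.0462) were higher in SB-LDN. ISL1 stood at 44.0 ± 7.52 in SB-LDN and 1.55 ± 0.144 in SB-CHIR. SLC17A6 was higher in SB-LDN, at 111.6 ± 5.55 against 19.4 ± 1.85. HOXA2 (0.0133 ± 0.0115 against 18.9 ± 1.28) and MEIS2 (2.59 ± 0.403 against 115.5 ± 2.12) were lower.

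By limma, 337 genes were higher and 820 lower in SB-LDN than in SB-CHIR, and 13789 did not pass. The groups did not overlap for 63.0% of the tested genes, where chance gives 10%. The genes higher made up 29.1% of the calls, and 42.3% under median-of-ratios scaling, with 452 higher and 616 lower. The largest increases were those of NEUROG2 (log2 difference 5.55, SE 0.125, adjusted p 1.03e-10), SIX3 (5.41), FEZF1-AS1 (4.66, with the same uncertainty of strand), RGS4 (26.5 ± 1.91 against 0.307 ± 0.11 FPKM) and the prohormone convertase gene PCSK1 (4.19). Among the largest decreases were those of NEUROG3 (-7.69, SE 0.106, adjusted p 1.77e-12), MEIS2 (-5.03), HOTAIRM1 (-4.99) and HOXA2 (-4.29). MALAT1, NEAT1, RNA18S5 and RNA28S5 were all lower in SB-LDN than in SB-CHIR, and with the MALAT1 and NEAT1 score as a covariate 174 genes were higher and 98 lower.

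Several regional lists were higher by camera in SB-LDN than in SB-CHIR, and none of the calls in this comparison held with an estimated correlation. Of 10 diencephalic genes 6 rose, SIM1 (3.54), LHX9 (3.21), BARHL2 (2.53) and IRX1 (2.45) in front (3.11e-05), of 15 cortical genes 5 rose, TBR1 (2.26), BCL11A (1.25), NR2F2 (1.23), NR2F1 (1.10) and RORB (1.08) (0.000595), and none of 12 neural progenitor genes passed (0.00468), with adjusted p = 0.0684 with an estimated correlation for each. Of 23 peripheral sensory genes 10 rose, ISL1 (4.13), DRGX (2.62) and EYA1 (2.19) in front (7.33e-05), and of 7 cholinergic genes ISL2 (1.88) and MNX1 (1.87) rose (0.000595), with adjusted p = 0.0585 with an estimated correlation for both. NR2F1 fell short without SB-LDN replicate 1, at 0.97. Of 10 telencephalic genes 5 rose, among them SIX3, LHX2 (2.44), OTX2 and FEZF1, which was listed at 0 in each SB-CHIR library and at 10.8, 12.4 and 10.01 FPKM in SB-LDN (0.00195, and adjusted p = 0.0664 with an estimated correlation). Of 12 dorsal interneuron genes 7 rose, LHX1 (3.21) and LHX9 in front, and 1 fell (0.000426, and adjusted p = 0.135 with an estimated correlation). Of 15 proneural genes 5 rose and 2 fell, NEUROG1 (-3.18) in front (0.0111, and adjusted p = 0.341 with an estimated correlation).

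Of 4 HOX genes of paralogs 1 to 5, 3 fell in SB-LDN relative to SB-CHIR, HOXA2 and HOXB2 (-1.05) among them (camera adjusted p 0.000595, 0.294 without the filter in a range of 0.000216 to 0.294, and adjusted p = 0.0676 with an estimated correlation). HOXB2 fell short at -0.96 without SB-CHIR replicate 3, -0.98 without SB-LDN replicate 1 and -0.99 under median-of-ratios scaling. Of 10 immediate early genes FOS (1.62) and EGR1 (1.22) rose (0.0413, and adjusted p = 0.489 with an estimated correlation). That list lost its call without SB-CHIR replicate 1 (0.0583), SB-CHIR replicate 2 (0.0715) or SB-LDN replicate 2 (0.121). It also did so with a pseudocount of 0.1 (0.0519) and under median-of-ratios scaling (0.065), in a range of 0.0174 to 0.121 over its alternatives. FOS lost its own call without any 1 of the SB-CHIR replicates or SB-LDN replicate 1 or 2, with adjusted p 0.0553 to 0.131, in a range of 0.00321 to 0.131.

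No call was made by camera for the other lists between SB-LDN and SB-CHIR. Counts of genes higher and lower were 0 and 1 of 18 pluripotency (camera adjusted p 0.282), 0 and 1 of 24 cell cycle (0.326), 1 and 0 of 24 pan-neuronal (0.983), 0 and 1 of 21 presynaptic (0.802), 0 and 1 of 16 postsynaptic (0.536), and 2 and 2 of 22 channel genes (0.983). Transmitter and regional lists had 3 and 2 of 13 ionotropic glutamate receptor (0.135, called without the filter in a range of 0.0232 to 0.269), 1 and 0 of 5 glutamatergic (0.854), 2 and 0 of 3 GABAergic (0.319, called without the filter in a range of 0.00249 to 0.463), 2 and 1 of 6 monoaminergic (0.143), 1 and 1 of 3 midbrain (0.812), 0 and 0 of 6 hindbrain (0.875) and 1 and 1 of 5 caudal axial genes (0.983). They were 1 and 0 of 11 neural crest (0.983), 0 and 1 of 10 autonomic (0.854), 0 and 0 of 9 astrocyte and oligodendrocyte (0.159), 0 and 0 of 8 mesenchyme (0.854), 0 and 0 of 11 epithelial (0.854), 0 and 0 of 8 WNT target (0.847), 1 and 0 of 13 BMP and TGF-beta target (0.558), 1 and 1 of 8 retinoic acid (0.854) and 0 and 0 of 13 unfolded protein genes (0.432). Adjusted over the list alone, all counts in this comparison were identical. A list's median, mean and test never differed in sign where camera made a call in any of the 6 comparisons. Among lists without a call they did so in 0, 3 and 1 lists against H9 in unpatterned, SB-CHIR and SB-LDN neurons, in 5 and 3 lists against unpatterned neurons in SB-CHIR and SB-LDN, and in 3 lists between the pre-patterned groups.

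HOX expression was also summed over the 32 HOX genes measured, as a readout of posterior identity. The sum was 0.143 ± 0.0451 FPKM in H9, 7.41 ± 0.523 in unpatterned neurons, 27.1 ± 1.99 in SB-CHIR and 1.21 ± 0.302 in SB-LDN (n = 3 each). A two-sided exact permutation test gave p 0.1 for each of the 6 comparisons, the smallest that 3 against 3 libraries allow. The SB-CHIR sum rested on HOXA2, without which its log2 ratio to unpatterned neurons was 0.16 instead of 1.87. Genes of paralogs 6 to 13 were near 0 in all libraries, with HOXD8 at 0.28 FPKM the highest value, and HOXB4, HOXB9 and CDX2, which mark more posterior levels, were too low to be tested, as were EMX2 and EN1, of the cortex and the midbrain-hindbrain border. In unpatterned, SB-CHIR and SB-LDN neurons EMX2 stood at 0.653 ± 0.0503, 0.0667 ± 0.0451 and 0.35 ± 0.0985 and EN1 at 0.0333 ± 0.0252, 0.0767 ± 0.0643 and 0.133 ± 0.0153, and EN1 was listed at 0 in each H9 library.

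The overlap of the differences of both pre-patterned groups from unpatterned neurons was tested in a fit of the 9 neuron libraries. Of the genes called against unpatterned neurons, 201 moved in the same direction in SB-CHIR and SB-LDN, 76 higher and 125 lower, and 7 in opposite directions. PRPH, TLX3, LHX9 and ISL1 were lower in both pre-patterned groups. Independent lists of these sizes would share 9.58 higher and 5.27 lower genes. The log2 differences of the 14946 genes correlated at 0.41 across genes, which are not independent replicates, with covariance 0.0958. In 20 simulations of unchanged groups with shared simulated controls, 0 genes were shared, the mean correlation was 0.50 and the mean covariance 0.0101, a difference in covariance of 0.0856. Each gene was drawn on its own, so hardly any could be called, and a control library that deviates in many genes was not imitated. The simulated groups held no changed genes, so their correlation comes from the shared controls alone. It is no measure for data with changed genes, and no conclusion is drawn from the correlations. The 3 control libraries cannot be split into parts of 2 or more, so part of the excess may come from the shared controls.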

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

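The tests of the ratio of NEUROG3 to NEUROG2, of the pan-neuronal list, of SB-LDN RNA and of pluripotency genes in H9 replicate 1, and the use of a nuclear RNA score, were chosen after the results were seen.

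In the fit of all 12 libraries, 5 genes passed by limma in opposite directions in SB-CHIR and SB-LDN against unpatterned neurons. They were selected for this and for passing between SB-LDN and SB-CHIR. The difference of SB-LDN from SB-CHIR follows from the values against unpatterned neurons, so its size and adjusted p by limma are no separate support. The prohormone convertase gene PCSK1 differed by 4.19 (SE 0.115, adjusted p 4.27e-10), with -1.89 in SB-CHIR and 2.30 in SB-LDN. BHLHE22, a neuronal transcription factor gene, differed by 3.79 (SE 0.108, adjusted p 6.16e-10), with -2.18 and 1.62. The receptor gene GPR50 differed by 3.09 (SE 0.211, adjusted p 1.18e-06), with -1.17 and 1.92. DDC, a decarboxylase of monoamine synthesis, differed by 2.43 (SE 0.0866, adjusted p 4.62e-09), with -1.28 and 1.15. The homeobox gene SHOX2 went the other way, with a difference of -3.57 (SE 0.137, adjusted p 8.38e-09) from 2.17 in SB-CHIR and -1.40 in SB-LDN.

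NEUROG2 was lower and NEUROG3 higher in the 3 SB-CHIR libraries than in the other 6 neuron libraries. Reads of NEUROG2 assigned to NEUROG3 would make both rise together, but NEUROG3 was at least 158% of NEUROG2 in SB-CHIR and at most 0.00524% in the other neurons, and 5 of 1352 words of 25 bases of the NEUROG3 transcript (0.37%) occur in NEUROG2. Fewer converted cells would lower neuronal genes as well, yet the median pan-neuronal gene differed by -0.062 (quartiles -0.31 and 0.24) while NEUROG2 differed by -5.03. With the mean log2 value of MALAT1 and NEAT1 as a nuclear RNA score in the model, NEUROG2 still differed by -5.13 (95% confidence interval -5.72 to -4.53), against nuclear RNA content as the whole cause. An effect of pre-patterning on either gene, or another inducing construct in these cultures, may each account for the values, and both stay open and untested because they move with the group. The same limit holds for every difference of SB-CHIR from another group, the genes shared with SB-LDN included.

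Genes higher in SB-CHIR than in unpatterned neurons outnumbered genes lower, at 824 and 467. GC content and transcript length were argued against as the whole cause, since 713 genes were higher and 440 lower after their trends were removed. The higher genes kept 95.8% of their median log2 difference (93.6% to 97.3% when each neuron library was left out). Of the higher genes 94.9% had both values. They were selected for their difference in the same data, so the share kept bears little on the excess. Scaling between libraries could account for part of the excess and stays open, because median-of-ratios scaling gave 626 higher and 560 lower, or 1.12 higher per gene lower. Nuclear RNA content stays open too, since with the score 500 genes were higher and 487 lower, so the excess was almost gone. The higher genes kept 79.5% of their median (74.7% to 83.4%), from 1.29 to 1.02, with 761 of 824 differences positive. Of these genes 400 stayed called, as the median SE went from 0.16 to 0.22. The score moves with the group, so an effect of pre-patterning, which was not tested, may underlie both. Ribosomal RNA values and estimated depth moved with the group as well, and whether either contributes to the excess was not tested.

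The anterior genes FEZF1, SIX3, LHX5 and HESX1 were high in H9 replicate 1, LHX5 and HESX1 being chosen after their values were seen, at 21.5 and 28.4 FPKM against 2.70 and 1.44 in replicate 2 and 0.23 and 0.92 in replicate 3. RNA from an SB-LDN library is argued against, since NEUROG2 reached 0.0347% of its SB-LDN mean in that library and SIX3 49.6%. Loss of pluripotency genes is argued against as well, with a median log2 difference of -0.0038 (quartiles -0.24 and 0.24) from the mean of replicates 2 and 3. A small share of cells with anterior gene expression might give such values and stays open. No biological explanation was tested, because the design holds no group within H9.

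For each comparison the 6 libraries allow 10 splits, too few for a share under 0.05. Each other split mixes both groups and puts their difference into the spread. Low counts there were therefore bound to occur, and no conclusion is drawn from them. The real split called 6939, 7577 and 7087 genes for unpatterned, SB-CHIR and SB-LDN neurons against H9, where the highest of the other splits called 0, 2 and 0. Against unpatterned neurons it called 1291 genes in SB-CHIR and 340 in SB-LDN, with 4 and 3 in the highest other split. Between SB-LDN and SB-CHIR it called 1157, with 0 in the highest other, and 1 split, the real one, reached the real value in each of the 6 comparisons.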

How the results depend on the processing

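The nuclear RNA score, the removal of small and ribosomal RNA genes and the 12-library fit of the shared genes were chosen after the data were seen. Alternative values of named genes, and their ranges, come from all alternatives except the fit without a filter. The named genes were in part selected for large differences, and a gene called in neither fit counts as kept. Of 14454 alternative values of named genes, 14068 kept their side of the thresholds, 115 no longer passed and 270 newly passed. In 1 more the sign reversed with a call, for SIX3 in unpatterned neurons against H9, at 1.09 without H9 replicate 1 (leave-one-out range -0.99 to 1.09). A change of sign was not marked where neither fit made a call. FEZF1-AS1 in that comparison, for example, stood at -0.84 in the fit of only the 6 libraries and at 0.27 without H9 replicate 1. With the inter-gene correlation estimated, 4, 2, 6, 1, 5 and 0 lists were called instead of 18, 14, 14, 10, 17 and 10, in the order unpatterned, SB-CHIR and SB-LDN against H9, SB-CHIR and SB-LDN against unpatterned, and SB-LDN against SB-CHIR. A pseudocount of 0.1, which weighs low genes more, gave 1516 higher and 827 lower genes in SB-CHIR and 344 and 296 in SB-LDN against unpatterned, 655 and 1601 in SB-LDN against SB-CHIR, and 400 shared genes. TPM scaling gave 779 lower genes in SB-CHIR and 276 higher and 256 lower in SB-LDN against unpatterned, and 594 and 1238 in SB-LDN against SB-CHIR. It raises all values against the same pseudocount and filter, so these counts do not show an effect of scaling between libraries alone. The nuclear RNA score gave 500 higher genes in SB-CHIR than unpatterned, and 174 and 98 in SB-LDN against SB-CHIR. The summed HOX ratio to unpatterned of 1.87 in SB-CHIR became 0.16 without HOXA2, its most abundant gene, and 0.10 as a mean of log2 values, which weighs all HOX genes alike, and that of -2.61 in SB-LDN became -0.13 as such a mean. Except for these constructions, the cause was not tested. Other counts stayed within 1.5 times, and the 12-library fit gave 199 shared genes.

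Leaving out 1 library gave 3003 to 3169 higher and 3777 to 3911 lower genes in unpatterned, 3699 to 3871 and 3763 to 3802 in SB-CHIR and 3117 to 3208 and 3886 to 4001 in SB-LDN against H9. Against unpatterned it gave 711 to 1060 and 443 to 495 in SB-CHIR and 172 to 188 and 142 to 186 in SB-LDN, and 324 to 365 and 719 to 961 in SB-LDN against SB-CHIR. Lists called were 18, 14 to 16, 14, 7 to 11, 15 to 19 and 9 to 10, shared genes 189 to 228, and HOX ratios 1.82 to 1.92 and -2.75 to -2.42. Values are FPKM without counts, so genes with few fragments carry errors that cannot be given here.

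With the replicate number as a block, 3105 and 3840, 3794 and 3782, 3156 and 3933, 826 and 469, 171 and 177, and 338 and 826 genes were higher and lower, 18, 14, 14, 10, 19 and 10 lists were called, and 203 genes were shared. The block changed list calls only in SB-LDN against unpatterned, for mesenchyme (adjusted p 0.0379, range 0.00067 to 0.323) and unfolded protein genes (0.0414, range 0.00544 to 0.214). Same-numbered libraries deviated together by over 0.1 in 8 of 18 pairs (correlations -0.243 to 0.281), and 0 libraries correlated best with their own number in every other group. All 3 pairs of SB-LDN against H9 were over 0.1 (0.281, 0.219 and 0.119), where the block changed no list call. Not every pair was over 0.1, so the numbers were not used as pairing in the main fit, and whether Exp in the titles marks an experiment shared by the groups stays open.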

Other observations

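The gene sets and lists below were chosen after the data were seen, the sets being 1188 from the annotation in the deposited table, tested in each comparison among the neurons. No called set kept its call with an estimated correlation when adjusted over all sets.

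GABA receptor genes were higher by camera in SB-LDN than in unpatterned neurons, a call that rests on the preset correlation. Of 11 genes annotated with GABA receptor activity, 5 rose and none fell, those that rose including GABRB2 from 3.08 ± 0.363 to 14.8 ± 2.22 FPKM (1.94), GABRQ (1.11) and GABRB1 (1.10), with a median of 0.74 over the set (n = 3 each, limma's camera adjusted p 5.09e-06, but adjusted p 0.989 with an estimated correlation). Against SB-CHIR 6 of the 11 rose in SB-LDN, with a median of 1.08 (adjusted p 0.000961, but adjusted p 0.976 with an estimated correlation), whereas none passed by limma between SB-CHIR and unpatterned neurons, where GABRB2 (0.80, adjusted p 0.000205), GABRA2 (-0.76, adjusted p 0.00155) and GABRQ (-0.73, adjusted p 0.000657) stayed below the required difference. The set of ligand-gated ion channel activity, with 10 genes, had 4 higher in SB-LDN than in unpatterned neurons (camera adjusted p 0.000102, but adjusted p 0.989 with an estimated correlation). Its median was also 0.74. The genes it shares with the GABA receptor set were not counted, so it is not read as a separate result.

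In SB-CHIR, chromatin and splicing sets were lower by camera than in unpatterned neurons by small amounts, with the preset correlation only. Of 52 genes of nucleosome organization 1 rose and 4 fell, with a median of -0.38 (camera adjusted p 0.00341, but adjusted p 0.949 with an estimated correlation). Of 110 spliceosomal genes 1 rose and 1 fell (median -0.19, adjusted p 0.0165, but adjusted p 0.949 with an estimated correlation), and of 20 helicase genes 1 fell (median -0.30, adjusted p 0.0229, but adjusted p 0.949 with an estimated correlation).

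A hypothesis of lower hypoxia and glycolysis genes in SB-LDN, raised by genes already seen, was tested on 25 other genes, of which 24 were tested. None rose and 1 fell against unpatterned neurons, with a median of -0.37, and camera gave p 0.00601 but p 0.46 with an estimated correlation, so a lower programme may be present and stays open. A hypothesis of a hypothalamic programme in SB-LDN, raised in the same way, was tested on 22 other genes, of which 7 were tested, and was not borne out, with a median of -0.23 against unpatterned neurons, the direction down and camera p 0.405.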
